A study of Mus musculus with 4 samples.

How the data were processed

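Mouse pancreas organoids of 5 lines, untreated and perhexiline-treated, were profiled by droplet single-cell RNA sequencing with multiplexing oligos. Per the labels, organoids were dissociated with Accutase and libraries were made with a 10x Genomics 3′ protocol. The labels list 4 samples, an expression and an oligo library for each of 2 pools, and the deposited values are 10 matrices of UMI counts per gene and cell barcode, 1 for each line and treatment. The matrix names and the series design gave line and treatment. Cell Ranger 6.1.1 and the mm10 genome are stated in the submitters' processing notes and the file headers, and the multiplexing tables gave the oligo and, by the library names inside them, the pool of each matrix. The oligos counted in each matrix were checked against these tables, whose own numbers run opposite to those of the pools. Steps of the authors beyond read counting and assignment of cells to oligos were not stated. The dose, duration and vehicle of perhexiline were not given in the sources used here. Per the growth protocol, KSC and KPSC can be kept without Noggin and A83-01, so medium can go with Smad4 status.

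Each matrix held 32285 gene entries and 12 oligo entries. The oligo entries, 11.1% of UMIs, were left out of library sizes and tests. Cells with at least 1000 UMIs, 500 genes and at most 20% mitochondrial UMIs were kept, 18210 of 19025 barcodes. Kept UMIs were 13447818 to 52695944 per matrix, and at these totals the 95% Poisson interval of a gene at 23.7 CPM in WT ran from 22.4 to 25. Scrublet, as run through scanpy, called 66 doublets (0.362%), too few for it to be taken as working on these cells, so doublets were not removed. Gene positions were taken from GENCODE M21 on GRCm38.

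UMIs of all cells were summed per matrix. Comparisons were fitted with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test) in R 4.3.3 and repeated with DESeq2 1.42.0. Perhexiline was tested with the line as a block, since both matrices of a pair came from the same organoid line. That pairing comes from the matrix names. The interaction of treatment with Kras status, untreated mutant lines against WT, and Trp53 and Smad4 status among the untreated mutant lines were tested besides. Residual degrees of freedom were 4, 3, 3 and 1, and the biological coefficient of variation was 7.89% for perhexiline, 7.39% for the interaction, 46.7% for mutant against WT and 43.0% for the fit of Smad4 and Trp53. The single WT line was assumed to vary as the other lines do. WT came from the second pool and all mutant lines from the first, so pool could not be separated from Kras status. A gene passed with an adjusted p under 0.05 (Benjamini-Hochberg).

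Recovery was tested on simulated data by thinning counts of 200 genes, 50 at each of 1.5, 2, 4 and 8-fold. Recovery was 74, 98, 100 and 100% for perhexiline across lines and 34, 56, 90 and 94% for the interaction. It was 0, 4, 26 and 64% for mutant against WT, 0, 0, 40 and 64% for Smad4 and 0, 0, 22 and 76% for Trp53. False calls numbered 12, 3, 2, 2 and 0. Between genotypes, changes below 4-fold were therefore beyond these tests. Most changes of 4-fold and some of 8-fold were missed too, so few or 0 calls do not show that such changes were absent. A shift of −0.20 given to 1 list on KPC counts came back as −0.21, with 0 of the other lists beyond the random lists.

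Fixed lists, 29 in number, were written before the data were examined, as were the comparisons, the cell filter, the naming rule and most alternatives. They cover cholesterol synthesis, other SREBP2 targets, LXR targets, fatty-acid synthesis, fatty-acid oxidation, lysosome, integrated stress response and unfolded protein response. Others hold targets of ERK, p53, TGF-beta, BMP, NRF2 and Wnt, and genes of interferon response, immediate early response, glycolysis, nuclear and mitochondrially encoded respiratory chain, S phase and G2/M. The rest hold markers of ductal, gastric, mesenchymal, immune, fibroblast, acinar, endocrine and endothelial cells. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry. A list was adjusted over its own members alone as well as over all genes.

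With 1 library per line and treatment no p was computed for a single line. Within a line, log2 ratios of CPM with 1 added were used. List medians of members at 5 CPM or more were set against 10000 random lists, each gene drawn from its 100 neighbours in level, and intervals came from 1000 Poisson resamples. The rule of size asked for 50 CPM and a 2-fold ratio. From each comparison with calls the naming rule took up to 12 genes in each direction with the largest fold. Where the 5-line fit named none, it was applied to the 4-line fit after values were seen. Members of the lists were named as examples by size and level.

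Cells were thinned to 3000 UMIs for cell-cycle phase and for shares of cells with interferon UMIs, and phase was scored with scanpy 1.11.5. Phase shares were tested by exact permutation of sign over lines. Clusters came from 2000 variable genes, 30 components, 15 neighbours and Leiden (leidenalg 0.10.2) at resolution 0.5. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives covered normalization, test, low-count filter, all barcodes, a 10% mitochondrial limit, thinning with equal cell numbers (964 per matrix), G1 cells alone, no block, each line left out, a pseudocount of 5, a minimum of 10 CPM, a rule of 100 CPM and clustering resolution. The 4-line fit as a comparison of its own and its alternatives were added after values were seen. The oligo libraries as samples of their own and allele sequences were not analysed here.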

Results

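The data were droplet single-cell RNA counts from mouse pancreas organoids of 5 lines, each untreated and after perhexiline, in 10 matrices of 1 library per line and treatment. The lines were wild type (WT), KC (mutant Kras), KPC (mutant Kras and Trp53), KSC (mutant Kras, Smad4-null) and KPSC (mutant Kras and Trp53, Smad4-null). The matrices held 19025 barcodes, of which 18210 cells were kept, 996 to 3059 per matrix. Median depth was 11145 to 17634 UMIs and 3086 to 3792.5 genes per cell, and the median mitochondrial share was 1.46 to 3.43%. Both WT matrices came from a second pool and the 8 mutant matrices from a first pool, so every difference between WT and the mutant lines is also a difference between pools. Each line counted once in every test. The edgeR, DESeq2 and permutation p-values below measure only the spread between these lines. Camera p-values at the preset correlation set the genes of a list against other genes, so their size does not measure agreement between lines. The Poisson and binomial intervals cover counting error only.

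Epithelial transcripts prevailed in every matrix. The ductal keratins Krt8 and Krt18 led the ductal list, whose members summed to 10836 to 17355 CPM per matrix (CPM, parts per 10⁶ of the UMIs of a matrix). No matrix held a cell with 3 or more markers of fibroblasts, acinar cells or endothelial cells (upper 95% limits 0.121 to 0.370%), and 1 of 1706 KSC cells carried 3 or more immune markers. Cells with 3 or more endocrine markers numbered 19 in WT (0.621%) and 23 in WT after perhexiline (0.808%), and 0 in each mutant matrix. Ins2 lay at 17 CPM and Sst at 11.9 CPM in untreated WT. Acinar transcripts summed to 4.68 to 15.4 CPM, led by Cela1. The fibroblast list reached at most 4 CPM, in KSC and from Col1a2.

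Levels of the engineered genes were read in every matrix first. Smad4, the shared partner of the TGF-beta and BMP signal transducers (chromosome 18, 73639009 to 73703780), lay at 78.0 CPM in KC (95% interval 75.1 to 80.9) and 76.9 in KPC. KSC held 39.8 CPM (37.7 to 42.0) and KPSC 14.8 (13.1 to 16.7). The ratio KSC to KC was 0.511 (0.478 to 0.545) and KPSC to KPC 0.192 (0.168 to 0.219), each 1 library against 1 library. WT, whose Smad4 is intact by its label, held 27.8 CPM, 0.356 of KC (0.334 to 0.380), so low Smad4 was not confined to the Smad4-null lines. With cells thinned to 3000 UMIs, a Smad4 UMI was seen in 20.6% of KC cells, 12.2% of KSC cells, 3.07% of KPSC cells and 8.07% of WT cells. After perhexiline the Smad4 levels were 29.2 CPM in WT, 76.1 in KC, 76.3 in KPC, 40.5 in KSC and 15.8 in KPSC. Tags were taken near the 3′ end of transcripts, so residual Smad4 tags in KSC and KPSC neither check nor exclude a deletion of inner exons. One label of KPSC names Smad5 in place of the Smad4 of the series text. Smad4 was taken as the deleted gene, and every comparison by Smad4 status rests on that. Smad5 lay at 9.57 to 22.6 CPM. Its level in KPSC (22.6) was above that in KPC (16.3), but in KSC (9.57) it was below that in KC (19.5). A lower level in KSC than in KC was thus not particular to Smad4.

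Kras (chromosome 6, 145216699 to 145250239) lay at 23.7 CPM in WT (22.4 to 25) and at 87.3, 90.4, 107.85 and 101.667 CPM in KC, KPC, KSC and KPSC, ratios to WT of 3.69, 3.82, 4.55 and 4.29. A point allele cannot be checked by level. Perhexiline left Kras at 24.2 CPM in WT, 84.4 in KC, 91.2 in KPC, 115 in KSC and 103 in KPSC. Trp53 (chromosome 11, 69580359 to 69591873) was present in every line, at 84.2 CPM in WT, 85.1 in KC, 93.8 in KPC, 115 in KSC and 124 in KPSC. Perhexiline-treated matrices held 87.9, 86.3, 94.0, 123 and 99.5 CPM of Trp53 in the same order. The Trp53 allele itself was not readable from these levels either.

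**Figure D1:**
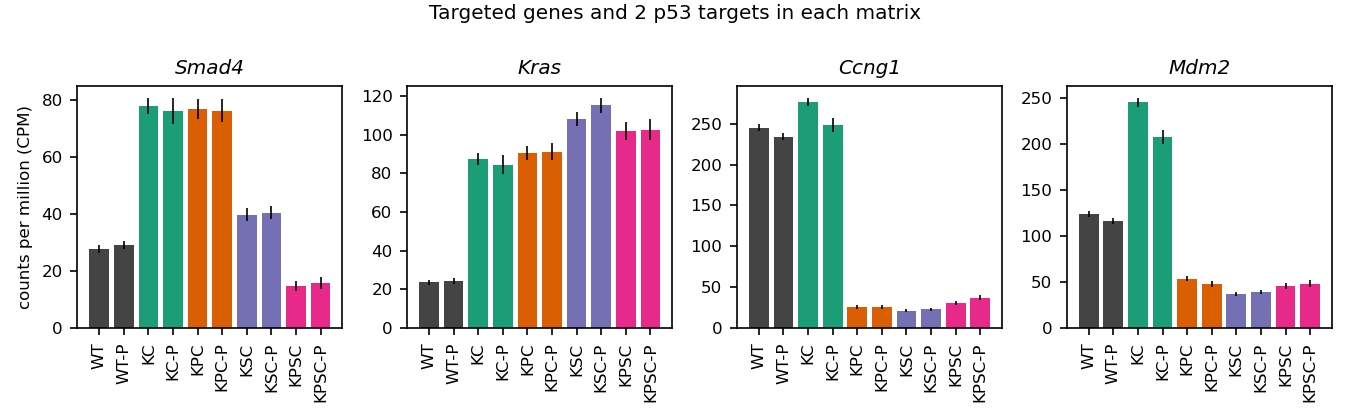
Levels of Smad4, Kras and the p53 targets Ccng1 and Mdm2 in CPM for each line, untreated and after perhexiline. Each bar is 1 matrix with its 95% counting interval. Smad4 lay at 14.8 in KPSC and 39.8 in KSC against 78.0 in KC, and at 27.8 in WT.

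Perhexiline, an antianginal drug that inhibits carnitine palmitoyltransferase and, as a cationic amphiphilic compound, gathers in lysosomes, was compared with no treatment within each line. In the 4 KRAS-mutant lines the genes of cholesterol synthesis were lower after perhexiline and those of the lysosome higher. Hmgcr, the rate-limiting reductase of the pathway (chromosome 13, 96648967 to 96670936), fell by 0.31 log2 units (SE 0.04, edgeR adjusted p = 0.0130, n = 4 lines, 4 of 4 lower). Acat2, which makes acetoacetyl-CoA, fell by 0.37 (SE 0.04, edgeR adjusted p = 0.0105), and the isomerase Idi1 fell by 0.37 (SE 0.05, edgeR adjusted p = 0.0182), each in 4 of 4 lines. Cd63, a tetraspanin of late endosomes and lysosomes (chromosome 10, 128900989 to 128912822), rose by 0.74 (SE 0.08, edgeR adjusted p = 0.00934), from 214.5 to 366.6 CPM in KPC and from 124.5 to 262.5 CPM in KPSC. Mt2, a metal-binding metallothionein, rose by 1.02 (SE 0.07, edgeR adjusted p = 0.00189), to 1064.9 CPM in KSC.

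With all 5 lines, WT among them, edgeR called 0 of 12666 genes for perhexiline. Unadjusted p under 0.05 was reached by 1481 genes, 787 higher and 694 lower, and the smallest adjusted p in edgeR was 0.2965. DESeq2 called 41 genes (26 up, 15 down). In the 4 mutant lines alone, edgeR called 375 of 12421 genes, 212 up and 163 down, with 2658 genes at unadjusted p under 0.05, and DESeq2 called 517, of which 310 were shared. That fit was planned as an alternative, and genes were chosen from it by the fixed naming rule after values were seen. Its count rested on single lines: without KPC 6 genes were called, without KPSC 12, without KC 210 and without KSC 368. Named gene models that moved in the same direction in all 4 lines numbered 343 of the 375, and 22 were unnamed models.

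The largest rises in the 4 mutant lines were at low levels. S100g, a calcium-binding protein, rose by 2.39 log2 units (SE 0.22, edgeR adjusted p = 0.00622), from 0.8 to 10.7 CPM in KPSC and from 1.7 to 9.6 CPM in KSC, while in WT it lay at 9.0 and 6.5 CPM. Oasl2, an interferon-induced oligoadenylate synthetase-like protein, rose by 2.29 (SE 0.47, edgeR adjusted p = 0.0412), with KC at 3.2 to 54.4 CPM and KSC at 2.1 to 2.4. Ccl5, a chemokine that attracts T cells, rose by 2.28 (SE 0.29, edgeR adjusted p = 0.0141), from 7.4 to 63.4 CPM in KC and from 3.9 to 28.1 CPM in KPSC. Further rises were in Ddx60 (2.05), Dhx58 (1.91), Sprr2d (1.58), Uts2 (1.52), Trim12c (1.45), Igtp (1.43), Oas2 (1.42), Fxyd5 (1.36) and Ly6g6c (1.25). Sprr2d, Trim12c and Ly6g6c have close relatives in the genome, so reads shared between copies make their levels less certain. Besides Cd63 and Mt2, genes above 100 CPM in some line that rose included Mt1 (0.80, SE 0.07), Muc1 (0.51, SE 0.05), Gdf15 (0.59, SE 0.06) and Lamp1 (0.34, SE 0.05).

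Among the genes that fell most was Lgr5, an R-spondin receptor of the Wnt pathway that marks progenitor cells (chromosome 10, 115450311 to 115587780). Lgr5 fell by 0.88 log2 units (SE 0.14, edgeR adjusted p = 0.0226, 4 of 4 lines), from 14.1 to 4.8 CPM in KPSC and from 23.1 to 14 CPM in KPC. Lpin1, a phosphatidate phosphatase that is also a target of SREBP, fell by 0.63 (SE 0.13, edgeR adjusted p = 0.0412), and Aldoc, a glycolytic aldolase, by 0.72 (SE 0.15, edgeR adjusted p = 0.0406). Ces2a had the largest fall, −1.3 (SE 0.21), at 0.9 to 0.4 CPM in KC and 3.7 to 1.4 CPM in KSC. Tm4sf20 fell by 0.98, S100a2 by 0.81, Prss35 by 0.73, Vsig1 by 0.69, Olfr655 by 0.66, Loxl2 by 0.63, Prkcg by 0.54 and Nadk2 by 0.54. Cftr, the chloride channel of duct cells, fell by 0.46 (SE 0.10, edgeR adjusted p = 0.0476), and the stress-induced transcription factor genes Jun and Fosb by 0.37 and 0.39 (SE 0.05 each).

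Cholesterol synthesis was the pathway the series was built around. Of its 20 tested genes, 20 were lower after perhexiline across the 5 lines (median −0.17), with 13 called when adjusted over the list alone and 0 over all genes. In the 4 mutant lines 20 of 20 were lower (median −0.22), 17 called over the list alone and 8 over all genes (camera adjusted p = 2.75e-18, and camera adjusted p = 0.253 with an estimated correlation). The 8 were Acat2, Hmgcs1, Hmgcr, Pmvk, Mvd, Idi1, Msmo1 and Dhcr7. Hmgcs1 fell by 0.27 (SE 0.06, edgeR adjusted p = 0.0417), Pmvk by 0.29, Mvd by 0.30, Msmo1 by 0.24 and Dhcr7 by 0.28. The abundant late gene Fdps lay 0.12 lower (SE 0.03, edgeR adjusted p = 0.0650) and Dhcr24 0.07 lower (SE 0.05, edgeR adjusted p = 0.495). Per line the median log2 ratio was 0.08 in WT (95% counting interval 0.06 to 0.09, 18 of 20 genes higher), −0.13 in KC (−0.19 to −0.12, 20 lower), −0.14 in KPC (−0.16 to −0.10, 17 lower), −0.25 in KSC (−0.27 to −0.21, 18 lower) and −0.25 in KPSC (−0.30 to −0.22, 19 lower). All 4 mutant medians lay below every one of 10000 random lists of matched level, and the WT median lay above every one. That rank was not particular to cholesterol synthesis. The G2/M list ranked the same way in every line, and the lysosome list ranked at the opposite ends. The camera test across the 5 lines gave adjusted p = 5.74e-13. That call was lost when gene correlation was estimated from the data, camera adjusted p = 0.343 with an estimated correlation.

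**Figure D2:**
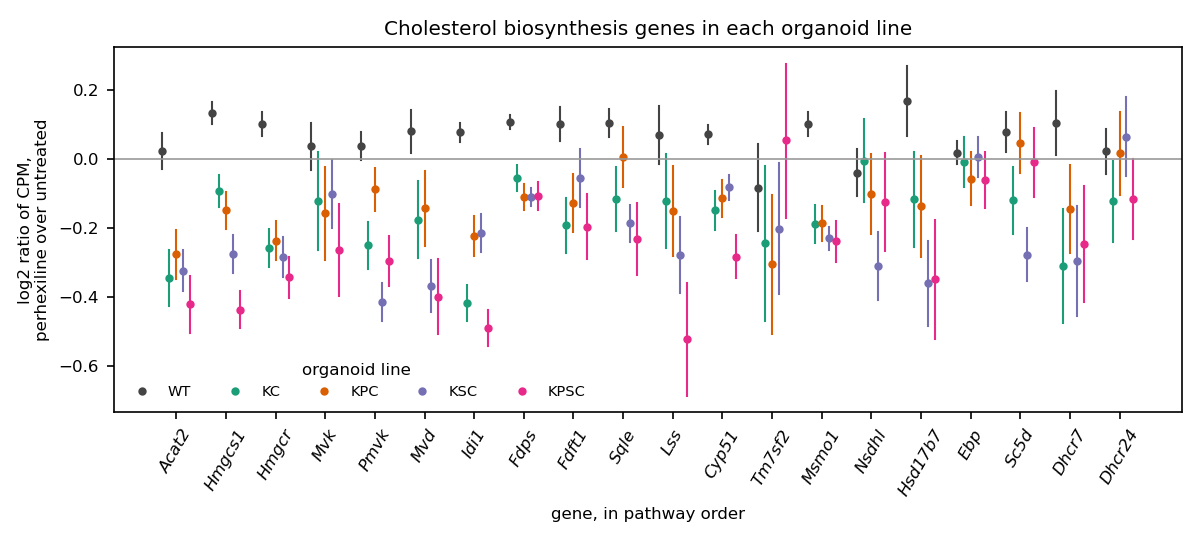
Log2 ratio of perhexiline to untreated for each gene of the cholesterol synthesis list, by line; each point is 1 pair of matrices with its 95% counting interval. Hmgcr lay at 0.10 in WT and at −0.26, −0.24, −0.28 and −0.34 in KC, KPC, KSC and KPSC.

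Related lipid genes moved less evenly. The other SREBP2 targets were lower in 6 of 6 genes across the 5 lines (median −0.11, 2 called over the list alone, 0 over all genes), with camera adjusted p = 0.000953, and camera adjusted p = 0.392 with an estimated correlation. Their line medians were 0.09 in WT (5 of 6 higher), −0.055 in KC (−0.104 to 0.003), −0.11 in KPC, −0.14 in KSC and −0.29 in KPSC. The median was −0.056 without KPSC and −0.16 without WT. In the mutant lines Stard4 fell by 0.38 (SE 0.06, edgeR adjusted p = 0.0247), whereas the LDL receptor gene Ldlr lay 0.14 lower (SE 0.06, edgeR adjusted p = 0.192). Fatty-acid synthesis was lower in 13 of 14 genes (median −0.13, 7 over the list alone, 0 over all genes, camera adjusted p = 1.08e-05, and camera adjusted p = 0.343 with an estimated correlation). Its members Acss2, Elovl6 and Acly fell by 0.52, 0.31 and 0.26 in the mutant lines, 5 of 14 over all genes, while Scd1 lay at −0.07 (SE 0.07). Line medians of fatty-acid synthesis were 0.002 in WT (6 of 12 higher), −0.11 in KC, −0.04 in KPC, −0.11 in KSC and −0.18 in KPSC. Without KPSC the median of this list was −0.085. Fatty-acid oxidation, the process perhexiline is known to block, was lower in 12 of 17 genes (median −0.04, 0 over the list alone, camera adjusted p = 0.239). Hadha fell by 0.23 in the mutant lines (SE 0.05, edgeR adjusted p = 0.0398) and Cpt1a lay at 0.17 (SE 0.09, edgeR adjusted p = 0.332). Acadl, an abundant dehydrogenase of the list, lay 0.34 higher (SE 0.10, edgeR adjusted p = 0.0843, 3 of 4 lines higher), and line medians ran from −0.07 in KSC to 0.03 in KPSC (11 of 17 higher). The LXR targets, which rise when oxysterols gather, had 1 gene higher and 4 lower (median −0.02, camera adjusted p = 0.986).

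Lysosome genes ran the other way. Of 22 genes, 21 were higher across the 5 lines (median 0.19, 14 called over the list alone, 0 over all genes), with camera adjusted p = 3.53e-13, and camera adjusted p = 0.343 with an estimated correlation. The mutant lines had a median of 0.27, with 17 called over the list alone and 12 over all genes (camera adjusted p = 1.12e-22, and camera adjusted p = 0.217 with an estimated correlation). Among the 12 that rose were the hexosaminidase gene Hexa (0.91, SE 0.11), the sialidase gene Neu1 (0.42, SE 0.05), Lamp2 (0.40, SE 0.05) and the proton-pump subunit Atp6v0d1 (0.39, SE 0.06). Tfeb, the transcription factor that drives lysosome genes, lay at −0.08 (SE 0.11). WT had a median of −0.11 (−0.13 to −0.07, 20 of 22 lower), against 0.26 in KC (0.23 to 0.31, 21 higher), 0.24 in KPC, 0.30 in KSC and 0.44 in KPSC (0.38 to 0.49, 21 higher).

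Interferon-response genes had the largest ratios of any list, and they were not shared by all lines. Isg15, a ubiquitin-like antiviral modifier (chromosome 4, 156199424 to 156200818), went from 8.9 to 93.4 CPM in KC, from 27.4 to 79.8 in KPC and from 41.5 to 119.4 in KPSC, but lay at 8.4 and 6.2 in KSC and 1.5 and 2.3 in WT. Rtp4 rose in the mutant fit by 1.42 (SE 0.30, edgeR adjusted p = 0.0459, 3 of 4 lines) and Rsad2 by 1.79 (SE 0.38, edgeR adjusted p = 0.0457, 3 of 4 lines). Stat1 lay 1.05 higher (SE 0.26, edgeR adjusted p = 0.0646). Tap1, which loads peptides for antigen presentation, rose by 1.09 (SE 0.14, edgeR adjusted p = 0.0141, 4 of 4 lines). The median ratio of 11 members was 2.62 in KC (2.52 to 2.73), 1.48 in KPC (1.17 to 1.53) and 1.00 in KPSC (0.80 to 1.11), with 11 of 11 higher in each, against −0.03 in KSC (−0.12 to 0.08) and −0.04 in WT (−0.10 to 0.03). All 13 tested members were higher across the 5 lines (median 1.29, 12 over the list alone, 0 over all genes, camera adjusted p = 6.21e-12, and camera adjusted p = 0.343 with an estimated correlation). The mutant lines had 13 over the list alone and 3 over all genes. With cells thinned to 3000 UMIs, the share of cells with an interferon-list UMI went from 49.0 to 90.2% in KC, 45.8 to 67.9% in KPC and 57.1 to 74.7% in KPSC, against 23.1 to 24.7% in KSC and 33.7 to 31.7% in WT. The shares include any UMI from free RNA. The mutant lines shared 1 pool and so its free RNA, and in treated KSC the share was 24.7%. Treated KSC cells were deeper, with a median of 16486 UMIs against 11722.5 in KC, 11145 in KPC and 11147 in KPSC. Free RNA would thus be a smaller part of a KSC cell, so its share is no strict bound for the other lines. The interferon genes Ifnb1, Ifnl2 and Ifnl3 were too low to test.

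**Figure D3:**
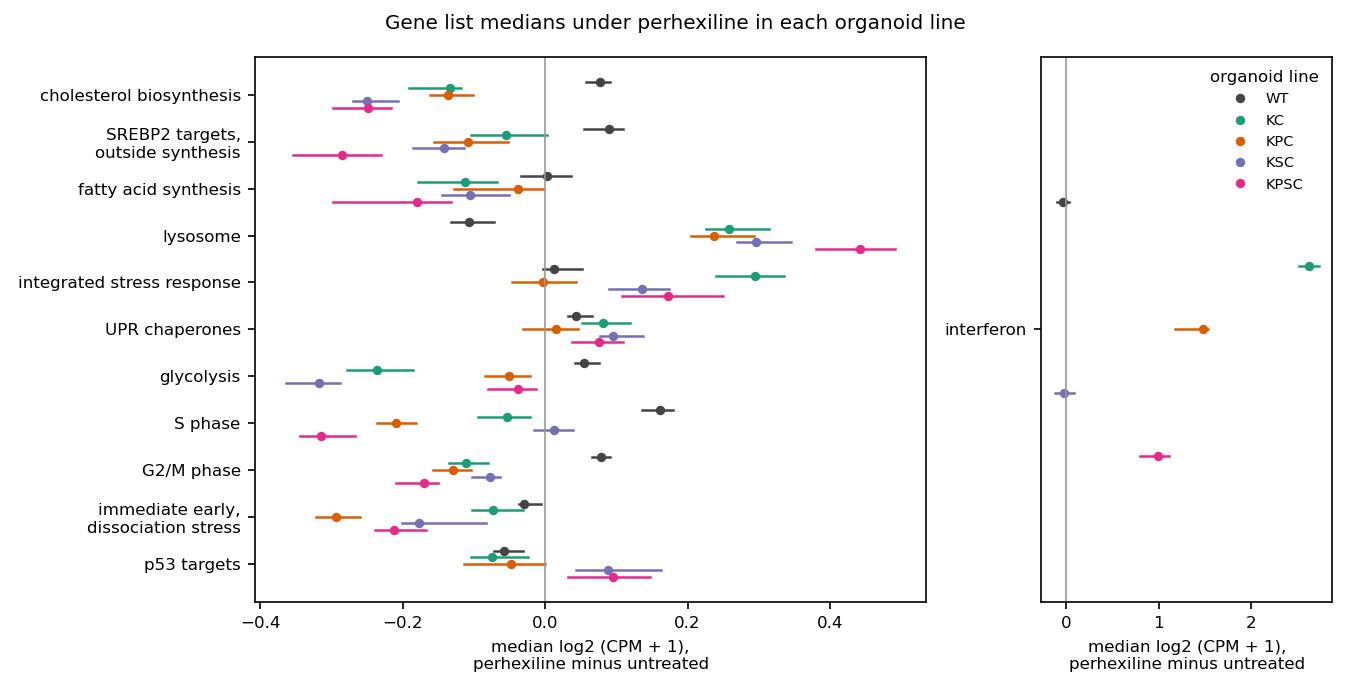
Median log2 ratio of perhexiline to untreated for the gene lists in each line, with 95% counting intervals. The cholesterol synthesis median lay at 0.08 in WT and −0.25 in KPSC, and the interferon median at 2.62 in KC and −0.03 in KSC.

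Proliferation genes were slightly lower in the mutant lines and higher in WT. Of the G2/M list 51 of 52 were lower across the 5 lines (median −0.11, 0 over the list alone, camera adjusted p = 5.74e-13, and camera adjusted p = 0.392 with an estimated correlation). In the mutant lines 34 were called over the list alone and 7 over all genes: Top2a fell by 0.26 (SE 0.04), Mki67 by 0.28 (SE 0.05) and the spindle motor gene Kif11 by 0.35 (SE 0.06). The S-phase list had 40 of 42 lower (median −0.10, 0 over the list alone, camera adjusted p = 4.96e-07, and camera adjusted p = 0.475 with an estimated correlation), and in G1 cells alone it was not called (camera adjusted p = 0.977). G1 cells were called by low scores for the S-phase and G2/M lists themselves, so that loss was built in and decides nothing. G2/M medians per line were 0.08 in WT (48 of 52 higher), −0.11 in KC, −0.13 in KPC, −0.08 in KSC and −0.17 in KPSC. S-phase medians were 0.16 in WT (41 of 42 higher), −0.05 in KC, −0.21 in KPC, 0.01 in KSC and −0.32 in KPSC. The share of cells in G1 went from 38.8 to 33.9% in WT, 48.9 to 54.1% in KC, 20.1 to 28.7% in KPC, 14.1 to 17.9% in KSC and 20.7 to 36.9% in KPSC. The mean change was 5.81 points (SD 7.69, 4 of 5 lines higher, exact permutation p = 0.1875, and 0.281 adjusted over the 3 phases). The mutant lines alone gave 8.49 points (SD 5.56, exact permutation p = 0.125, the smallest that 4 pairs allow). G2/M changed by −4.76 points on average (SD 5.74, exact permutation p = 0.125) and S by −1.05 (SD 2.47, exact permutation p = 0.4375). With 5 pairs the smallest exact permutation p was 0.063, so no share could have passed.

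**Figure D4:**
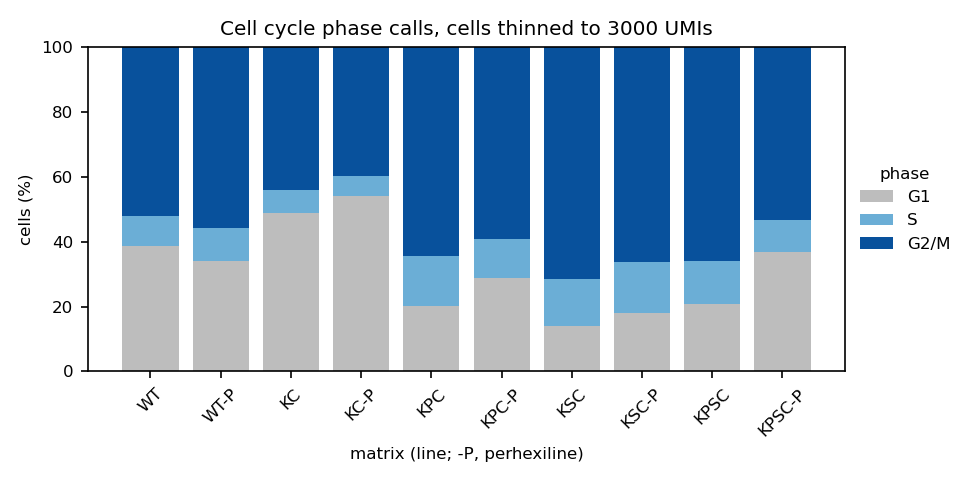
Percent of cells assigned to each cell-cycle phase per line, untreated and after perhexiline, with cells thinned to 3000 UMIs. The G1 share went from 20.7 to 36.9% in KPSC and from 38.8 to 33.9% in WT.

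Stress and energy lists were mixed, and some of their line medians were as large as those of cholesterol synthesis. Integrated stress response genes were higher in 11 of 14 (median 0.10, 2 over the list alone, 0 over all genes, camera adjusted p = 0.000697, and camera adjusted p = 0.343 with an estimated correlation), with Chac1, a glutathione-degrading enzyme, up by 0.35 in the mutant lines (SE 0.07) and Atf4 at −0.03 (SE 0.04). Line medians were 0.29 in KC (12 of 14 higher), 0.17 in KPSC and 0.14 in KSC, but 0.01 in WT and −0.003 in KPC (7 of 14 higher). Without KC the median of the list was 0.06. In G1 cells alone the list was not called (camera adjusted p = 0.123), though its median was still 0.10. Unfolded protein response genes were higher in 13 of 16 (median 0.05, 0 over the list alone, camera adjusted p = 0.0419, and camera adjusted p = 0.343 with an estimated correlation). That call was also lost without WT, KC or KSC (camera adjusted p = 0.208, 0.138 and 0.105), and the median was −0.02 in G1 cells (camera adjusted p = 0.777). Immediate early genes were lower in 8 of 11 (median −0.16, 7 over the list alone, 0 over all genes, camera adjusted p = 2.45e-06, and camera adjusted p = 0.343 with an estimated correlation). Their line medians were −0.29 in KPC, −0.21 in KPSC, −0.18 in KSC, −0.07 in KC and −0.03 in WT. Glycolysis was lower in 15 of 16 (median −0.14, 0 over the list alone, camera adjusted p = 1.20e-06, and camera adjusted p = 0.392 with an estimated correlation), with line medians of −0.32 in KSC, −0.24 in KC, −0.05 in KPC and −0.04 in KPSC, against 0.06 in WT (13 of 16 higher). Nuclear genes of the respiratory chain were lower in 17 of 20 (median −0.04, camera adjusted p = 0.0233, and camera adjusted p = 0.475 with an estimated correlation). Mitochondrially encoded ones were lower in 9 of 13 (median −0.03, 2 over the list alone, camera adjusted p = 0.0186, and camera adjusted p = 0.475 with an estimated correlation), with mt-Nd3 down by 0.33 in the mutant lines (SE 0.06). Their line medians were 0.04 in WT (10 of 13 higher) and 0.05 in KPSC, against −0.135 in KC, −0.06 in KPC and −0.12 in KSC. Against the random lists, the glycolysis medians of KPC and KPSC ranked at percentiles 9.58 and 31.5. The mitochondrially encoded median of KPC ranked at 19.3, so none of these stood out. The median of the mitochondrially encoded genes was −0.055 without KPC and −0.052 without KPSC. Without KSC both respiratory lists lost their calls (medians −0.03 and −0.04, camera adjusted p = 0.222 for nuclear and 0.152 for mitochondrial genes), and without KC the mitochondrial list did (median −0.02, camera adjusted p = 0.284), with medians close to those of all 5 lines.

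The remaining lists were not called across the 5 lines. By median and camera adjusted p they were ERK targets (−0.05, 0.185, 15 of 20 lower), p53 targets (−0.03, 0.403, 14 of 22 lower), TGF-beta targets (0.05, 0.239, 7 of 11 higher) and BMP targets (−0.05, 0.392, 4 of 5 lower). NRF2 targets (0.01, 0.986), Wnt targets (−0.05, 0.385), ductal genes (0.01, 0.988), gastric genes (−0.09, 0.185), mesenchymal genes (0.10, 0.227) and immune genes (−0.01, 0.858) were not called by camera adjusted p either. Without KPSC the gastric list was called (median −0.21, camera adjusted p = 0.00864). Fibroblast, acinar, endocrine and endothelial lists had fewer than 3 tested members. In all, camera called 13 of 25 lists, 4 up and 9 down, and 0 with an estimated correlation; the smallest fry adjusted p was 0.207. In the 4 mutant lines fry passed for the lysosome (adjusted p = 0.0318), G2/M (0.0318) and cholesterol synthesis lists (0.0355). Among single p53 targets, Trp53inp1 rose by 0.44 in the mutant lines (SE 0.08) and Btg2 fell by 0.31 (SE 0.05).

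By the rule of size, which asks for 50 CPM and a 2-fold ratio within 1 line, 32 gene calls were made. WT had 0 of 2829 genes. KC had 12 higher and 1 lower of 2685, led by Isg15 (log2 ratio 3.26), Ifi27l2a (2.78), Irf7 (2.62), Bst2 (1.94), Rnf213 (1.76) and B2m (1.28). KPC had Isg15 higher (1.51) and the mucosal peptide gene Tff3 lower (−1.58). KSC had Lor (1.29), Slpi (1.21) and Ptgs1 (1.02) higher and the oxidase gene Ero1l lower (−1.21). KPSC had 12 higher and 1 lower of 2837, among them Sprr1a (1.51), Isg15 (1.5), Mt2 (1.34), Spink4 (1.26), Capg (1.24) and Anxa10 (1.16). The rule carries no error term between cultures, as each line and treatment had 1 library.

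Whether perhexiline acts in a way specific to mutant Kras, the question the series title raises, was asked by the interaction of treatment with Kras status. Hmgcr had an interaction of −0.40 log2 units and Cd63 of 0.88, with 4 mutant lines against 1 WT line. In edgeR 0 of 12666 genes were called, 1007 had unadjusted p under 0.05 (540 higher in the mutant lines, 467 lower), and the smallest adjusted p was 0.2923. DESeq2 called 31 genes (21 higher, 10 lower). For cholesterol synthesis 20 of 20 genes had the lower change in the mutant lines (median −0.30, 12 over the list alone, 0 over all genes, camera adjusted p = 9.50e-15, and camera adjusted p = 0.358 with an estimated correlation). For the lysosome list 22 of 22 had the higher change (median 0.45, 14 over the list alone, 0 over all genes, camera adjusted p = 3.98e-20, and camera adjusted p = 0.247 with an estimated correlation). S-phase genes (42 of 42 lower, median −0.32, camera adjusted p = 7.41e-23, and camera adjusted p = 0.529 with an estimated correlation) and G2/M genes (52 of 52 lower, median −0.23, camera adjusted p = 2.13e-19, and camera adjusted p = 0.247 with an estimated correlation) also differed.

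Interferon genes had a higher change in the mutant lines for 13 of 13 members (median 1.46, camera adjusted p = 9.32e-06, and camera adjusted p = 0.529 with an estimated correlation), although KSC lay beside WT. The other 6 lists called by camera for the interaction, with their adjusted p, were glycolysis (−0.24, 1.25e-05), SREBP2 targets (−0.24, 0.000612), fatty-acid synthesis (−0.18, 0.00136), mitochondrially encoded respiratory genes (−0.14, 0.00136), immediate early genes (−0.16, 0.00313) and nuclear respiratory genes (−0.05, 0.0473). Of these 6, the smallest camera adjusted p was 0.529 with an estimated correlation, so 0 of the 11 lists held. Over 2787 genes the changes in WT had rank correlations of −0.246 with KC, −0.444 with KPC, −0.199 with KSC and −0.530 with KPSC, whereas pairs of mutant lines had 0.353 to 0.669. Pearson coefficients were 0.123, −0.227, −0.256 and −0.144 for WT with the same lines, so the sign for KC depended on the measure. Those coefficients are over genes, not replicate lines. Only 1 WT line was present and it was captured in its own pool, so mutant Kras and pool could not be told apart.

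Untreated KRAS-mutant lines were set against untreated WT next, to ask what mutant Kras changes at baseline. Ifitm3, an interferon-induced membrane protein, rose by 5.59 log2 units (SE 0.39, edgeR adjusted p = 0.0405), from 0.3 CPM in WT to between 12.6 and 18.1 in the mutant lines. St3gal6, a sialyltransferase, rose by 4.18 (SE 0.26, edgeR adjusted p = 0.0405), from 7.9 CPM in WT to between 118.5 and 157.6. Mtus2 fell by 6.17 (SE 0.25, edgeR adjusted p = 0.0117), as did Akr1b7 (−5.54, SE 0.27), Sptssb (−4.39, SE 0.31) and Sema5a (−7.48, SE 0.49), which lay near the counting floor in the mutant lines. These were the 6 genes that edgeR called of 14485, 2 up and 4 down. Unadjusted p under 0.05 was reached by 2123 genes (1225 higher, 898 lower), and DESeq2 called 1215 (877 up, 338 down). The edgeR count was 65 without KSC and 0 without KC, KPC or KPSC.

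The ERK feedback genes Etv4 and Etv5, which mark active Kras signalling, lay at 9.0 and 3.9 CPM in WT and at 18.2 to 23.4 and 9.8 to 12.5 CPM in the mutant lines. ERK targets were higher in 14 of 20 (median 0.48, camera adjusted p = 0.0532) and cholesterol synthesis genes were level, 10 higher and 10 lower (median 0.06, camera adjusted p = 0.933). Interferon genes were higher in 11 of 13 (median 3.67, 8 over the list alone, 0 over all genes, camera adjusted p = 2.74e-05, and camera adjusted p = 0.663 with an estimated correlation). Fatty-acid oxidation was lower in 17 of 17 (median −0.48, 2 over the list alone, 0 over all genes, camera adjusted p = 1.58e-05, and camera adjusted p = 0.639 with an estimated correlation). Endocrine genes were lower in 4 of 5 (median −9.02, 4 over the list alone, 0 over all genes, camera adjusted p = 2.35e-07, and camera adjusted p = 0.639 with an estimated correlation). Integrated stress response genes were higher in 10 of 14 (median 0.67, 4 over the list alone, 0 over all genes, camera adjusted p = 0.00390, and camera adjusted p = 0.663 with an estimated correlation). Mitochondrially encoded respiratory genes were lower in 12 of 13 (median −0.57, camera adjusted p = 0.00605, and camera adjusted p = 0.701 with an estimated correlation). The other 22 of 27 lists were not called. Summed interferon transcripts lay at 142 CPM in WT against 249 in KC, 256 in KPC and 344 in KPSC, but at 106 in KSC, below WT. Bst2 alone held 98.3 of the 142 CPM in WT, so the interferon median of 3.67 rests on members that were low there. By the rule of size KC differed from WT in 186 genes up and 147 down of 2756, KPC in 177 and 169 of 2818, KSC in 210 and 269 of 2734, and KPSC in 197 and 176 of 2852.

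Trp53 status among the untreated mutant lines showed in the p53 targets, though not along the lines that the labels draw. Cyclin G1 (Ccng1, chromosome 11, 40748552 to 40755311) lay at 277 CPM in KC and 25.8 in KPC and 30.9 in KPSC, but also at 21.3 in KSC, which is Trp53-intact by label. Mdm2, the p53 ubiquitin ligase (chromosome 10, 117688875 to 117710758), lay at 245, 53.4, 37.3 and 45.2 CPM in KC, KPC, KSC and KPSC. Phlda3 lay at 245, 23.0, 36.9 and 27.5, Eda2r at 31.7, 1.9, 1.1 and 0.9, and the arrest gene Cdkn1a at 640, 150, 244 and 143. In WT Ccng1 lay at 245 CPM and Mdm2 at 124. The p53-target median was −1.68 for KPC against KC (19 of 20 lower), 0.26 for KPSC against KSC, −2.17 for KSC against KC (20 of 20 lower, −2.21 to −2.11) and −0.10 for KPSC against KPC. edgeR called 0 of 13046 genes for Trp53 status, 277 had unadjusted p under 0.05 (147 higher, 130 lower), and DESeq2 called 56 (29 up, 27 down).

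Camera called 9 lists for Trp53 status. The p53 targets were lower in 20 of 22 (median −1.18, camera adjusted p = 6.17e-15, and camera adjusted p = 0.797 with an estimated correlation), with 0 called over the list alone and 0 over all genes. Mitochondrially encoded respiratory genes were lower in 13 of 13 (median −0.73, camera adjusted p = 5.24e-10), interferon genes higher in 12 of 12 (median 0.81, camera adjusted p = 7.04e-06) and NRF2 targets lower in 10 of 11 (median −0.52, camera adjusted p = 0.000255). Each of these 3 had camera adjusted p = 0.797 with an estimated correlation. The interferon difference came from 1 pair, with medians of −0.04 for KPC against KC (5 of 11 higher) and 1.77 for KPSC against KSC (11 of 11). For NRF2 targets the pairs gave −0.39 and −0.05, and for the mitochondrially encoded genes −0.23 and −0.92. The S-phase list (0.22, camera adjusted p = 0.0127) had adjusted p = 0.882 with an estimated correlation. Immediate early (0.46, 0.0131), TGF-beta (0.34, 0.0425), stress response (−0.21, 0.0475) and mesenchymal lists (−1.89, 0.0478), each with its camera adjusted p, had adjusted p = 0.797 with an estimated correlation. The stress response went opposite ways in the pairs, 0.42 for KPC against KC (12 of 14 higher) and −0.76 for KPSC against KSC, and S phase lay at 0.64 and 0.08. The mesenchymal fall came from KSC (1361 CPM summed, against 49.4 in KPSC), while KPC (46.9) lay above KC (37.3). The comparison rests on 2 lines against 2 with 1 residual degree of freedom.

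Smad4 loss among the untreated mutant lines gave 0 of 13046 genes in edgeR, 352 at unadjusted p under 0.05 (149 higher, 203 lower) and 86 in DESeq2 (30 up, 56 down). Pmepa1, a feedback inhibitor of TGF-beta signalling (chromosome 2, 173224458 to 173276533), lay at 34.5 CPM in KC, 6.6 in KPC, 16 in KSC and 238 in KPSC. Id1, a BMP target, lay at 35.7 in KC and 246 in KSC, and at 52.5 in KPC and 107 in KPSC. Smad7 lay at 17.5, 33.5, 26.6 and 48.1, and Serpine1 at 11.9, 16.6, 19.0 and 58.0 in KC, KPC, KSC and KPSC. KSC stood apart in cell identity: vimentin (Vim, chromosome 2, 13573927 to 13582826) lay at 1067 CPM against 13.6 to 16.4 in the other mutant lines, and the gastric peptides Tff1 and Tff2 at 335 and 1202 CPM against at most 13.1 each in those lines, while WT held 90.3 and 333. Onecut1 lay at 0.1 CPM in KSC and 0.4 in KPSC, against 5.0 in KC and 8.6 in KPC.

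The TGF-beta and BMP target lists were higher in the Smad4-null lines, unevenly between pairs. TGF-beta targets were higher in 9 of 11 (median 0.57, camera adjusted p = 0.00828) and BMP targets in 4 of 5 (median 1.21, camera adjusted p = 0.0104). Each had camera adjusted p = 0.790 with an estimated correlation. The TGF-beta median was 0.60 for KPSC against KPC (10 of 10 higher) and 0.19 for KSC against KC (5 of 10 higher). The BMP median was 2.35 for KSC against KC (3 of 3 higher) and 0.27 for KPSC against KPC (2 of 3 higher). The p53 targets (−1.10, camera adjusted p = 4.02e-11), S phase (0.23, 0.00190), mesenchymal genes (2.42, 0.00343) and G2/M (0.27, 0.00911) were also called by camera adjusted p, and each had adjusted p = 0.790 with an estimated correlation. These 4 calls came from the pair of KSC and KC. In 3 of them KC was the line apart. Summed S-phase transcripts lay at 1717 CPM in KC against 2650 to 2743 in the other mutant lines, and G2/M at 5300 against 7191 to 7584. Summed p53 targets lay at 4600 CPM in KC against 1130 to 1299. The mesenchymal genes alone set KSC apart. KSC against KC gave 0.47 for S phase and 0.42 for G2/M, while KPSC against KPC gave −0.04 and −0.01, and p53 targets differed as given above. Summed mesenchymal transcripts lay at 1361 CPM in KSC, 37.3 in KC, 49.4 in KPSC and 46.9 in KPC. By the rule of size KSC and KC differed in 134 genes up and 213 down of 2629, and KPSC and KPC in 38 up and 32 down of 2804, with Pmepa1, Cxcl1, Ccl2 and Fst among the higher. The growth protocol allows KSC and KPSC to be kept without Noggin and A83-01, inhibitors of BMP and TGF-beta signalling, so medium can go with Smad4 status.

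Clustering of all cells gave 9 clusters, 8 of them over 90% from 1 line (7 of 9 with predicted doublets removed). A cluster of 37 WT cells, led by AY036118, had Sst and Mafb among its top genes. Its median depth was 4713 UMIs, 0.33 of that of its matrices, and its mitochondrial share 0.058%, so it was not named endocrine. A cluster of 524 cells, 99.6% from KSC, had Tff1 and Tff2. A cluster of 223 cells (1.22%) from all lines was led by B020031M17Rik, Sp110, Tcstv3 and Tcstv1, genes of the mouse 2-cell embryo. Its median depth was 2243 UMIs, so it was left unnamed. At resolution 1.0 the same genes led 62 cells with a median of 12463 UMIs, and a separate 167 cells led by Gm26917, Gm42418 and Lars2 had a median of 1887. Resolution 1.0 gave 16 clusters, among them 71 cells with the goblet genes Muc2, Zg16, Fcgbp and Clca1 (88.7% from KPC) and 34 cells led by Ccl5, Rsad2 and Ifit1 (41.2% from KPSC). Clusters were not tested between treatments, as each line had 1 library per treatment.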

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

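Kras in untreated WT lay at 23.7 CPM, apart from 87.3 to 107.85 in the mutant lines. It was the 1 value set apart from its group among 39 groups checked, where 1.95 would be set apart by chance. WT was captured in its own pool, and the cause was not tested. In the multiplexing counts, an oligo assigned to no matrix (CMO306) held 1.72% of oligo UMIs in the first pool, and CMO303 held 2.96% in the second.

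The change under perhexiline differed between the mutant lines and WT in 11 lists by camera. Their medians were −0.295 for cholesterol synthesis, −0.241 for other SREBP2 targets, −0.179 for fatty-acid synthesis, 0.453 for the lysosome, −0.242 for glycolysis, −0.0478 for nuclear and −0.138 for mitochondrially encoded respiratory genes, −0.322 for S phase, −0.232 for G2/M, 1.46 for interferon response and −0.159 for immediate early genes. With an estimated correlation 0 of the 11 held, the smallest camera adjusted p being 0.247.

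The list tests of the interaction were planned, and of the explanations weighed here, tests of a small group of cells, a depth difference, splits of the 4 mutant lines and shared reads were written before their result was seen. The tests of immune cells, mutant Kras, cycling cells, the pool of WT, splits of the 5 lines, free RNA and damaged cells were chosen after the result was seen.

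Interferon genes were higher under perhexiline in KC, KPC and KPSC. Contaminating immune cells could raise such genes in a few droplets, but the share of KC cells with an interferon UMI was 41.3 points higher under perhexiline, and 0 cells of treated KC, KPC or KPSC held 3 immune markers. Free RNA of the shared pool would reach KSC cells too, where the share was 24.7% under perhexiline. KSC cells were deeper, however, so free RNA would weigh less in them, and this share is no strict bound for the other lines. A small group of cells was tested too, and the 5% of cells richest in these UMIs held 21.5% of them in treated KC, 30% in KPC and 25.1% in KPSC. The median in KSC was −0.0259, but this lack of a rise is part of the pattern and rests on 1 pair of libraries, so a dependence on mutant Kras, and the cause of the rise, stay open.

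Cholesterol genes were lower and lysosome genes higher in the 4 mutant lines, and the opposite held in WT. Fewer cycling cells could lower cholesterol genes, but G1 cells alone gave a mean mutant median of −0.23, and for a depth difference between matrices, thinning cells to 3000 UMIs gave −0.21. Kras status and the pool of WT cannot be told apart, since no WT pair was in the mutant pool, and the lysosome list had a camera adjusted p of 0.247 for the difference with an estimated correlation (3.98e-20 with the preset one). Chance cannot be excluded over all 5 lines. Of 100 splits, the real one among them, 10 gave at least the real 1481 genes at unadjusted p under 0.05 (highest other 2597). As many lists as the real 13 came from 8 of them (highest other 13). Of the 14 that part every pair the numbers were 2 and 1, again with the real one. The other of these 2 exchanged the labels of WT alone (2584 genes), which is the opposite direction in WT given above. Splits that leave a pair together rest only on the lines they part, and can keep the real labels in those lines. Only the 14 can therefore weigh chance, and they are too few to exclude it. Some of the splits that leave pairs together gave equal fits, so the 100 are not all separate. For the 4 mutant lines the real split was the 1 of 32 with 375 called genes (highest other 18), and 1 of the 8 that part every pair. Here too only the 8 can weigh chance, and 1 of 8 is the smallest share they allow.

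Cells with transcripts known from the 2-cell embryo, 51 with 10 or more UMIs of 11 genes, were seen in 9 of 10 matrices. Free RNA would be spread over cells: such cells held 95.5% of these UMIs in untreated KC and 93.4 to 94.8% in WT, KPC and KPSC, but 38.9% in KSC and 42.7% in treated KC, so free RNA stays open for part of them. Shared reads within 1 gene family could mimic the state: cells picked by Tcstv1 and Tcstv3 held 91.0% of the UMIs of the other families in KC, the only line the test named, but 17.4% in KSC and 32.3% in treated KSC, so a bound set on KC alone was too narrow and shared reads stay open in KSC. Their median mitochondrial share was 3.78%, under the 10% set for damage (in KC 4.19 against 2.45% in the other cells), and depth was 1.04 of that of the other cells. Picking cells by UMIs favours deep ones, however, and a cluster of 223 cells led by the same genes had a median of 2243 UMIs. At resolution 1.0 these genes led 62 cells, with medians of 12463 UMIs and 3.78% mitochondrial UMIs. A separate 167 cells, led by Gm26917, Gm42418 and Lars2, had a median of 1887 UMIs. The depth of the 62 cells argues against damage in them, and damage stays open for cells outside the 62.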

How the results depend on the processing

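Calls for perhexiline across 5 lines went from 0 to 41 with DESeq2, 673 without a count filter, 55 after thinning, 7 in G1 cells, and 0 to 375 with 1 line left out, the 375 being the 4 mutant lines only (517 there with DESeq2). Without the line as a block the count was 0 too, with 28 genes at unadjusted p under 0.05 against 1481 with the pairing. The interaction gave 31 with DESeq2, 279 without a filter, 1 after thinning and 0 to 1 with a line left out. Mutant against WT gave 1215, 24, 1 and 0 to 65 in the same order, and 2 in the perhexiline matrices. Smad4 status gave 86 and Trp53 status 56 with DESeq2. The 4-line fit gave 1458 without a filter and 6 to 368 with a line left out. Lists called with an estimated correlation numbered 0, for 5 lines and for 4. The rule of size gave 32 gene calls summed over lines, 15 at a minimum of 100 CPM and 71 in G1 cells, and resolution 1.0 gave 16 clusters. Of 660 list medians under alternatives 13 reversed sign. In G1 cells these were, in WT, unfolded protein response −0.0106, G2/M −0.0165 and immediate early 0.0504, in KC, S phase 0.145 and G2/M 0.0278, in KPC, SREBP2 targets 0.0541, BMP −0.0844 and S phase 0.0355, in KSC, p53 targets −0.0330 and G2/M 0.0413, and in KPSC, TGF-beta −0.0196. Thinning reversed p53 targets in KC (0.00648) and fatty-acid oxidation in KSC (0.00272). G1 cells were picked by the S-phase and G2/M lists, so the reversals of these lists in G1 cells carry no separate result. The cause of the others was not tested.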

Other observations

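Cells with transcripts of the 2-cell embryo, such as Zscan4, Tcstv1, Tcstv3 and Zfp352 family genes, were found in untreated cultures of every line. They numbered 42 of 10388 untreated cells and 9 of 7822 treated cells, with the highest share in KC, 19 of 2722 cells (0.698%) untreated and 2 of 996 (0.201%) after perhexiline. WT had 3 of 3059 and 0 of 2847 (upper 95% limit 0.129%). The genes of this list were picked after the values were seen. Free RNA and shared reads stay open in KSC and some treated matrices. Damage stays open for cells outside the 62 that these genes led at resolution 1.0.

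Treated KPC held less Tff3 (log2 ratio −1.58), and at resolution 1.0 a group of 71 cells, 88.7% from KPC, carried the goblet genes Muc2, Zg16, Fcgbp, Clca1 and Spink4. In WT the genes Taf10 and Ube2m lay at 35.8 and 42.6 CPM, against 317 to 401 and 207 to 246 CPM in the mutant lines. Of 2787 genes, 32 lay at least 4-fold above WT in all 4 mutant lines, 12 of them with a spread under 1.5-fold among those lines, and 9 lay as far below.

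The following tests were chosen after the result was seen. If these cells are a true cell state, which stays open, perhexiline might lower their share: 5 of 5 lines had the lower share under treatment, with a mean of −0.283 points (SD 0.183) and an exact permutation p = 0.063, the smallest that 5 pairs allow, so the test cannot tell. More lines, or replicate cultures of KC, would settle it.

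The KSC line may carry an altered Trp53 although its label gives it as intact. Its p53 targets lay 2.17 log2 units below those of KC (median −2.17, 20 of 20 lower), as low as in KPC and KPSC (KPSC against KPC −0.10). Ccng1 lay at 21.3 CPM in KSC and 277 in KC. The value is consistent with loss of p53 function in KSC, but a lower p53 drive without an altered allele would give the same levels, and reading the Trp53 transcript for variants would separate them. If it holds, the comparisons by Trp53 and Smad4 status have 1 line, KC, with working p53 among the 4 mutant lines.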
